A study of Mus musculus with 24 samples.

How the data were processed

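The data are 24 microarrays of the Affymetrix Mouse Gene ST type, which measure mRNA from embryoid bodies of the 46C mouse embryonic stem cell line. Per the labels' protocols, differentiation began on gelatin-coated dishes on day 1 with LIF, the aggregates moved to low attachment culture on day 3, were plated on day 7 and received a serum-free medium from day 8. Untreated EBs and EBs treated with FK506 and cyclosporin A were each collected at days 4, 6, 8 and 12, which gave 8 groups of 3 arrays.

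Per the submitters' processing notes, the authors made the deposited values with robust multiarray average (RMA) in Affymetrix Expression Console. Versions, library files and genome build are not given in the sources used here. The deposited table holds log2 values for 35556 probe sets with 1 column per array, and the log2 scale was taken from their range, since no label names it. Arrays have no read depth, and no detection calls came with the table, so low signals were not shown to lie above background. The number of arrays limits the precision: the median SE of a treatment difference was 0.09 on the log2 scale. No pair of arrays was identical, the smallest SD between a pair being 0.121.

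Probe sets were named from the platform's annotation, with symbols checked through Entrez identifiers against the GRCm38.p6 gene table. In that annotation 21789 probe sets had 1 symbol, 1621 had several and 12146 were not listed. Of the 21789, 21698 matched the gene table and 0 symbols changed. Genes were taken from probe sets with 1 symbol, and of the 999 genes with more than 1 probe set the one with the highest mean over all arrays was used, which left 19938 genes. Probe sets with several symbols or none were not named. The brachyury gene (Tbxt), a fixed gene, had no probe set under that symbol and is not analysed here.

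Treatment effects were tested with limma 3.58.1 in R 4.3.3, with lmFit on a model of 1 mean per group over all 24 arrays (16 residual degrees of freedom), eBayes, and Benjamini-Hochberg adjustment within each contrast at a threshold of 0.05. The contrasts were treated against untreated at each day, untreated EBs between neighbouring days and from day 4 to day 12, the difference of the treatment effect between neighbouring days, and the mean treatment effect over the 4 days. The 28 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 112 tests of the 4 treatment contrasts (and apart from these over the untreated and over the interaction contrasts), and beside it with camera's estimated correlation and with fry. A list is said to have risen or fallen where camera with the preset correlation called it. The lists were neural progenitor, neuronal, naive pluripotency, primed epiblast, BMP-Smad target, BMP ligand, receptor and antagonist, primitive streak and mesendoderm, extraembryonic and definitive endoderm, cardiac muscle, endothelial and blood, mesenchyme and smooth muscle, surface ectoderm and epithelium, neural crest and trophoblast. The others were calcineurin-NFAT component, FGF-ERK response, Wnt response, Nodal-activin response, Notch response, anterior Hox, posterior Hox and Cdx, cell cycle, p53 response, unfolded protein response, hypoxia and glycolysis, cholesterol synthesis, immediate early and housekeeping. Correlations of the treatment effect with the untreated time course used days that share no array. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

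The comparisons, the lists, the named-gene rule and most other settings below were chosen before the data were examined. The named genes were, for each treatment contrast, the 10 largest rises and 10 largest falls among called genes whose 3 treated arrays all lay on one side of the 3 untreated ones, and for neighbouring untreated days the 5 largest each way. Also named were 17 fixed genes of neural, pluripotent, BMP and calcineurin biology, and of each list described up to 4 members with the smallest p. Gene models with clone names, small RNA genes and predicted pseudogenes were passed over among the largest changes.

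Same-numbered arrays were checked for pairing by the correlation of their deviations from the group means. It lay above the minimum of 0.1 for every number at day 6 (0.30, 0.14 and 0.21), day 8 (0.48, 0.55 and 0.11) and day 12 (0.12, 0.34 and 0.25), so the numbers were taken to pair the arrays there. Treated replicate 3 nevertheless correlated better with an untreated array of another number at day 8 (0.126 against 0.107) and at day 12 (0.264 against 0.253).

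The other settings tried were a filter at the 40th percentile of mean level, quantile normalization, centring on the median, the mean of a gene's probe sets, an intensity trend with robust prior, array weights, the replicate number as a block, a fit of the compared groups alone, each array left out in turn, a 2-fold threshold, other settings of the list tests, and Spearman's correlation. A replicate block within each day and a fit without the day 8 pair numbered 2 were added after seeing the data. The model was tested on simulated data for 19938 genes with 200 changed and the BMP-Smad list shifted besides. Noise was drawn independently for each gene and array, without the correlation between genes or the pairing of arrays seen in the data. The shares and false calls below therefore hold for such noise and need not hold for the real arrays. For day 6 it recovered 86.6% of genes changed 1.5-fold, 97.0% of those changed 2-fold and 100% of those changed 4-fold, with 10 false calls and 3 of list members among 202 in all. For day 12 the shares were 86.6%, 100% and 100%, with 12 false calls and 2 of list members among 205.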

Results

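Gene expression was measured in embryoid bodies (EBs), aggregates of differentiating embryonic stem cells, made from the mouse embryonic stem cell line 46C, which carries a fluorescent reporter in its Sox1 locus. Cultures were left untreated or were given FK506 (100 ng/ml) and cyclosporin A (1 ug/ml) from day 3 to day 8. These drugs block calcineurin, a calcium-dependent phosphatase that activates the NFAT transcription factors. RNA was collected at days 4, 6, 8 and 12, so the last day lies after the drug treatment ended. Each of the 8 groups held 3 arrays from 3 independent experiments, 24 arrays in all, and the number of arrays limits the precision. The median signal per array lay between 7.80 and 7.88 on the log2 scale. Group values below are log2 signals as mean ± SD (n = 3 arrays), differences are on the log2 scale with their SE, and adjusted p-values are those of limma's moderated test.

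The untreated EBs were compared between days to describe the course of differentiation on which the drugs acted. From day 4 to day 6 the primitive streak homeobox gene Mixl1 rose from 8.09 ± 0.23 to 11.69 ± 0.43, a difference of 3.60 (SE 0.38, adjusted p = 3.5e-07) or 12.1-fold. Cyp26a1 (3.17), Frzb (3.13), Aplnr (3.11) and Cer1 (3.05) rose with it, while Mcf2 (-2.19), Olfr307 (-2.14), Nexmif (-1.96), Hsd17b14 (-1.91) and Lefty1 (-1.91) fell. From day 6 to day 8 the embryonic globin gene Hbb-bh1 rose from 5.83 ± 0.11 to 10.76 ± 1.56 (difference 4.93, SE 0.49), followed by Ttr (3.27), Unc5c (3.25), Hba-x (3.15) and Bmp5 (3.05). Mal2 (-2.04), Tmem154 (-2.0), Mael (-1.87), Ppp4r4 (-1.71) and Sycp3 (-1.69) fell over the same days. From day 8 to day 12 the matrix proteoglycan gene Lum rose from 5.59 ± 0.50 to 10.35 ± 0.47 (difference 4.76, SE 0.49), with Dcn (3.95), Postn (3.79), Nrn1 (3.70) and Vtn (3.65). Pou5f1, which encodes the pluripotency factor Oct4, fell over those days from 11.68 ± 0.21 to 8.04 ± 0.34 (-3.64, SE 0.24, adjusted p = 1.08e-10), as did Mixl1 (-3.85), Foxh1 (-3.24), Cer1 (-3.18) and Zfp980 (-3.17). Between day 4 and day 12, Pax6 rose by 1.71, Nes by 1.77, Tubb3 by 1.03 and Id2 by 1.54, whereas Nanog changed by -3.34 and Fgf5 by -3.17.

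Gene lists fixed beforehand followed these genes in the untreated EBs. The primitive streak and mesendoderm list rose from day 4 to day 6 by a mean of 1.01 (14 of 19 members higher, 3 lower, and 14 and 4 adjusted over the list alone). It had adjusted p = 0.394 with an estimated correlation. The hypoxia and glycolysis list rose by 0.43 over those days (11 of 20 higher, 0 lower, and 11 and 0 adjusted over the list alone), with adjusted p = 0.283 with an estimated correlation. From day 6 to day 8 the list of BMP-Smad targets, genes switched on by bone morphogenetic protein signalling, rose by 0.96 (20 of 24 higher, 0 lower, 21 and 0 adjusted over the list alone), with adjusted p = 0.187 with an estimated correlation. Cardiac muscle genes rose by 0.78 between day 6 and day 8 (19 of 25 higher, 0 lower, 20 and 1 adjusted over the list alone), with adjusted p = 0.282 with an estimated correlation. From day 8 to day 12 the neural progenitor list rose by 1.02 (22 of 30 higher, 3 lower, 22 and 3 adjusted over the list alone) and the neuronal list by 1.27 (27 of 36 higher, 1 lower, 27 and 1 adjusted over the list alone), with adjusted p = 0.187 with an estimated correlation for both. The naive pluripotency list fell by 1.68 over those days on the log2 scale (0 of 25 higher, 25 lower, and 0 and 25 adjusted over the list alone), with adjusted p = 0.187 with an estimated correlation. In all, 4215 genes were higher and 4164 lower at day 6 than at day 4, 3544 and 3653 at day 8 than at day 6, 3749 and 3965 at day 12 than at day 8, and 5392 and 6018 at day 12 than at day 4. Of the changed genes, 50.3% were higher from day 4 to day 6, 48.6% from day 8 to day 12 and 47.3% from day 4 to day 12, against 30.6%, 29.1% and 27.8% after each array was centred on its median. That centring moved the median of all genes from day 4 to day 12 from -0.062 to -0.23. Fewer genes were called without untreated day 4 replicate 1 (2635 lower from day 4 to day 6), without untreated day 6 replicate 2 (2223 higher from day 6 to day 8) and without untreated day 8 replicate 1 (1940 higher from day 6 to day 8).

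At day 4, shortly after the drugs were added, treated and untreated EBs were compared to find the first genes to respond. Genes of the unfolded protein response list moved as a group. Many of them encode chaperones and folding enzymes of the endoplasmic reticulum, and others, such as Ddit3, Atf4 and Xbp1, encode transcription factors. Pdia6, a disulfide isomerase, stood at 11.84 ± 0.11 in treated and 11.48 ± 0.04 in untreated EBs (0.36, SE 0.06, adjusted p = 0.0606). Herpud1, a component of the pathway that degrades misfolded proteins, differed by 0.44 (SE 0.09, adjusted p = 0.136). Hyou1 differed by 0.31 (SE 0.06, adjusted p = 0.179) and Creld2 by 0.26 (SE 0.07, adjusted p = 0.579). With array weights the adjusted p-values of these 4 genes were 0.00177, 0.00666, 0.00181 and 0.0283, the lowest of their alternatives, whose highest were 0.937, 0.946, 0.937 and 1.00. Pdia6 also passed above the 40th percentile of mean level (0.0263) and with an intensity trend (0.00945). The list's mean shift was 0.23 and its median 0.20, with 20 of 20 members above 0, between 0.08 and 0.48. Of the 20 members 0 passed over all genes and 13 were higher adjusted over the list alone, with camera's adjusted p = 2.08e-16 and adjusted p = 0.00929 with an estimated correlation. In 18 members all 3 treated arrays lay above all 3 untreated ones and in 0 all lay below, where chance gives either outcome in 10% of genes. The members were read on the same arrays and are correlated, so they are not 20 separate tests of that 10%.

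Of the 19938 genes tested at day 4, limma called 1 higher and 0 lower, with 1128 at an unadjusted p under 0.05. That gene was Usp11 (probe set 10598933), a deubiquitinating enzyme, at 9.86 ± 0.08 in treated and 9.28 ± 0.10 in untreated EBs (0.57, SE 0.08, adjusted p = 0.00944) or 1.49-fold. Its call ended without untreated replicate 1 (adjusted p = 0.0857), treated replicate 1 (0.0736) or treated replicate 2 (0.171), under quantile normalization (0.0529) and with only the 6 day 4 arrays fitted (0.751), in a range from 7.66e-05 to 0.751 over its 15 alternatives. In each of these fits limma called 0 genes higher, with 1050, 430, 1723, 1093 and 806 genes in turn at an unadjusted p under 0.05. More were called above the 40th percentile of mean level (6 higher), with an intensity trend (5 higher) and with array weights (100 higher and 43 lower). The neural, pluripotency, BMP pathway and calcineurin genes fixed by name (Sox1 to Nfatc1) differed by -0.09 to 0.16, with adjusted p-values from 0.901 to 0.998. The endothelial and blood list was lower by a mean of -0.04 (0 of 27 members passed, and 0 adjusted over the list alone). It had camera's adjusted p = 0.00638 and adjusted p = 0.821 with an estimated correlation. Without untreated replicate 3 camera gave it 0.06, in a range from 0.000694 to 0.06. BMP-Smad targets (mean 0.01, median 0.05, 0 of 24 passed, 0 adjusted over the list alone) and neural progenitor genes (mean 0.01, median -0.01, 0 of 30 passed, 0 adjusted over the list alone) were not called (camera's adjusted p = 0.418 and 0.239). Camera set these lists below the other genes, whose median difference was 0.03, so the sign of its test differed from that of their mean. Both means turned negative, to -0.02, under quantile normalization and under centring on the median.

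**Figure D1:**
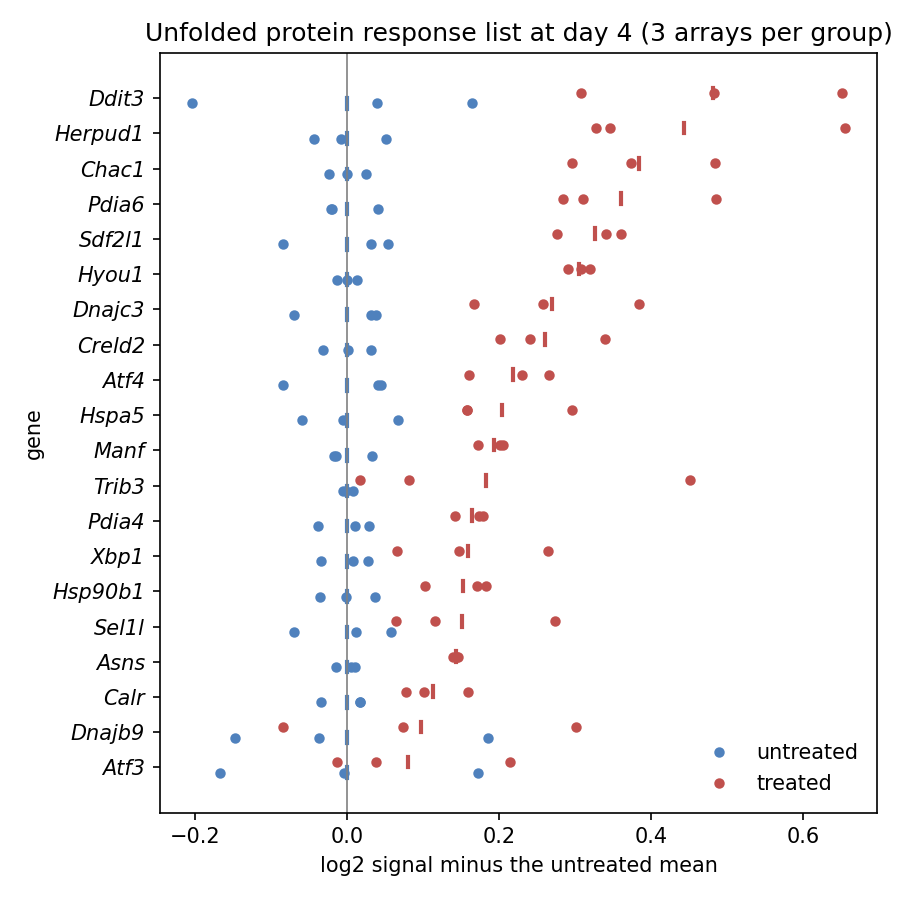
Log2 signal of the 20 members of the unfolded protein response list at day 4, each minus its mean in untreated EBs, with points for the 3 untreated (blue) and 3 treated (red) arrays and ticks for the means. The treated means of all 20 members lie above 0, between 0.08 and 0.48.

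At day 6 the comparison asked what the drugs did to the BMP pathway and to the mesodermal and neural programmes that it steers. Treated EBs held more mRNA of BMP-Smad targets and of a BMP ligand. Msx2, a homeobox gene switched on by BMP (probe set 10409314), stood at 10.43 ± 0.64 in treated and 8.31 ± 0.50 in untreated EBs, a difference of 2.12 (SE 0.27, adjusted p = 0.000216) or 4.35-fold. The ligand gene Bmp4 (probe set 10419261) stood at 11.50 ± 0.36 and 10.30 ± 0.26 (1.20, SE 0.16, adjusted p = 0.000216). Smad6, an inhibitor of the pathway that BMP itself induces, stood at 9.51 ± 0.49 and 8.34 ± 0.18 (1.16, SE 0.19, adjusted p = 0.00187). Id1 rose by 0.72 (SE 0.17, adjusted p = 0.0259) and Id2 by 0.64 (SE 0.13, adjusted p = 0.0116), while Id3 differed by 0.36 (adjusted p = 0.301). Foxf1, a forkhead gene of lateral plate mesoderm (probe set 10576046), had the largest rise named at this day, from 8.07 ± 0.28 to 10.76 ± 0.77 (2.69, SE 0.27, adjusted p = 1.7e-05) or 6.45-fold. Hand1, another lateral mesoderm regulator, rose from 8.42 ± 0.29 to 10.57 ± 0.78 (2.15, SE 0.30, adjusted p = 0.000441). Capn6 (2.19), Unc5c (2.09), Asb4 (2.01), Prdm6 (1.98), Pmp22 (1.93), Nrp1 (1.92) and Usp18 (1.90) rose with it. Falls were smaller, led by Tmem154 (-1.15, SE 0.19, adjusted p = 0.0018), Exoc3l (-1.05), Klhl4 (-1.04), Spon1 (-0.94), Rab25 (-0.83), Ebf1 (-0.78), Tubb4a (-0.78), Ltb (-0.76), Cdh9 (-0.75) and Sall2 (-0.75). Neural and pluripotency genes did not pass, with Sox1 at -0.08 (adjusted p = 0.821), Pax6 at -0.23 (0.646), Nes at -0.23 (0.674), Tubb3 at -0.10 (0.794), Pou5f1 at -0.22 (0.823), Nanog at -0.08 (0.949) and Fgf5 at -0.64 (0.501). Calcineurin genes did not pass either, with Rcan1, a known NFAT target, at 0.08 (0.872), Ppp3ca at 0.22 (0.166, but 0.0396 with array weights, in a range from 0.0396 to 0.516), Ppp3cb at 0.03 (0.943) and Nfatc1 at 0.37 (0.0733, but 0.0387 with the replicate block within day and 0.0428 without treated replicate 3, in a range from 0.0387 to 0.518). limma called 251 genes higher and 115 lower, and 418 and 303 with the replicate block within day. Of the calls 68.6% were higher, against 58.2% under quantile normalization. Counts were 79 higher and 19 lower without untreated replicate 2, 94 and 36 without treated replicate 1 and 155 and 32 without treated replicate 3. Without untreated replicate 3, 37 were lower. In 1 or more of these fits the calls of Spon1, Rab25, Ebf1, Tubb4a, Ltb, Cdh9, Sall2, Id1 and Id2 ended, at adjusted p-values from 0.0515 to 0.259, against 7.57e-05 to 0.259 over all their alternatives.

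Gene lists showed which programmes moved together at day 6. BMP-Smad targets rose by a mean of 0.72 (12 of 24 members higher, 0 lower, 16 and 0 adjusted over the list alone), with camera's adjusted p = 2.12e-18 and adjusted p = 0.114 with an estimated correlation. Its leading members were Tbx3 (1.76, SE 0.21), Msx2, Hand1 and Bmper (1.25, SE 0.20). The list of BMP ligands, receptors and antagonists rose by 0.18 (4 of 26 higher, 0 lower, 5 and 1 adjusted over the list alone). Bmp4, Bmp5 (1.74), Smad1 (0.54) and Bmp6 (0.33) passed, and the list had adjusted p = 0.253 with an estimated correlation. Primitive streak and mesendoderm genes rose by 0.40 (3 of 19 higher, 0 lower, 7 and 1 adjusted over the list alone). Mesp1 (1.54), Wnt3 (0.92) and Evx1 (0.60) passed, and the list had adjusted p = 0.458 with an estimated correlation. Wnt response genes rose by 0.35 (2 of 14 higher, 0 lower, 6 and 0 adjusted over the list alone). Apcdd1 (1.51) and Nkd1 (0.80) passed, and the list had adjusted p = 0.257 with an estimated correlation. The extraembryonic and definitive endoderm list rose by a mean of 0.24 but a median of 0.06, with 18 of 29 members above 0 (3 higher, 0 lower, 5 and 0 adjusted over the list alone). Pdgfra (1.42), Gata4 (1.23) and Cxcr4 (1.07) passed, and the list had adjusted p = 0.777 with an estimated correlation. Anterior Hox genes rose by 0.18 (2 of 18 higher, 0 lower, 3 and 0 adjusted over the list alone). Meis2 (0.90) and Hoxb2 (0.81) passed, and the list had adjusted p = 0.777 with an estimated correlation. Genes of cholesterol synthesis rose by 0.22 (3 of 16 higher, 0 lower, 6 and 0 adjusted over the list alone). Cyp51 (0.44), Nsdhl (0.43) and Sc5d (0.35) passed, and the list had adjusted p = 0.253 with an estimated correlation. The unfolded protein response list rose by 0.15 (1 of 20 higher, 0 lower, 3 and 0 adjusted over the list alone). Pdia6 (0.26) passed, and the list had adjusted p = 0.114 with an estimated correlation. Primed epiblast genes were lower by a mean of -0.27 (1 of 17 higher, 2 lower, 1 and 4 adjusted over the list alone). Foxd3 (-0.75) and Sall2 (-0.75) fell, Cdh2 rose against the list by 0.64, and the list had adjusted p = 0.458 with an estimated correlation. Camera also set lower the neuronal list (mean -0.11, 0 of 36 passed, 0 adjusted over the list alone, adjusted p = 0.777 with an estimated correlation) and the surface ectoderm list (-0.10, 0 of 22 higher, 1 lower, 1 and 4 adjusted over the list alone, adjusted p = 0.638 with an estimated correlation). In the surface ectoderm list the member that fell was Krt7 (-0.38). Hypoxia and glycolysis genes (-0.09, 0 of 20 passed, 0 adjusted over the list alone, adjusted p = 0.777 with an estimated correlation) and immediate early genes (-0.11, 0 of 20 passed, 0 and 1 adjusted over the list alone, adjusted p = 0.777 with an estimated correlation) were lower by the same test. The neural progenitor list had a mean of -0.05 and was not called (0 of 30 passed, 0 and 2 adjusted over the list alone, camera's adjusted p = 0.213 and adjusted p = 0.924 with an estimated correlation). Camera's calls ended without 1 array for 5 of these lists, at adjusted p-values of 0.0876 (without untreated replicate 2) and 0.0601 (treated replicate 3) for endoderm, in a range from 0.00253 to 0.0876. They were 0.0792 and 0.101 (without untreated replicates 2 and 3), 0.0794 and 0.152 (treated replicates 1 and 3) for anterior Hox (range 0.00998 to 0.152), and 0.0583, 0.0588 and 0.0615 (untreated replicates 1 and 3, treated replicate 2) for surface ectoderm (range 0.0121 to 0.0615). For hypoxia they were 0.061, 0.0504 and 0.187 (untreated replicates 1 and 2, treated replicate 2, range 0.007 to 0.187), and for immediate early genes 0.0734 (treated replicate 2, range 0.00707 to 0.0734). Array weights also ended camera's call of the hypoxia list (-0.085, adjusted p = 0.0504). Without untreated replicate 2 the calls of Foxd3, Smad1, Bmp6, Mesp1, Evx1, Wnt3, Cxcr4, Hoxb2, Meis2, Pdia6, Nsdhl and Sc5d ended (adjusted p-values of 0.0513 to 0.261), and without other arrays those of Wnt3, Krt7, Bmp6, Cxcr4, Hoxb2, Meis2, Pdia6 and Sc5d, against 0.000192 to 0.261 over all their alternatives. Quantile normalization ended the calls of Meis2, Hoxb2, Cdh9 and Krt7 (0.0526 to 0.0648).

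At day 8, the end of the drug treatment, the same groups were compared to see whether neural genes had fallen behind. Sox1, an early marker of neural fate, stood at 8.46 ± 0.04 in treated and 8.87 ± 0.05 in untreated EBs (-0.41, SE 0.09, adjusted p = 0.00531). Zic1, a zinc finger gene of early neural tissue, stood at 6.52 ± 0.09 and 7.62 ± 0.21 (-1.10, SE 0.17, adjusted p = 0.000736). Map2, which encodes a neuronal microtubule protein, stood at 7.55 ± 0.27 and 8.35 ± 0.16 (-0.80, SE 0.13). Pax6 fell by 0.55 on the log2 scale (SE 0.16, adjusted p = 0.0332), while Nes (-0.05, adjusted p = 0.901) and Tubb3 (0.17, adjusted p = 0.322) did not pass. Cer1, a secreted inhibitor of BMP and Nodal (probe set 10514083), had the largest fall named, from 10.26 ± 0.86 to 7.81 ± 1.01 (-2.45, SE 0.41, adjusted p = 0.00144). It was followed by Penk (-1.76), Pkd1l1 (-1.61), Trh (-1.42), Lgi1 (-1.38), Trp53i11 (-1.31), Zic2 (-1.30), Dmrta1 (-1.24), Samd3 (-1.23) and Tal2 (-1.13). Tbx4, a T-box gene of the allantois and hindlimb (probe set 10379944), rose from 8.78 ± 0.57 to 11.66 ± 0.54 (2.87, SE 0.24, adjusted p = 9.6e-07) or 7.32-fold. Next came Gpr50 (2.27), Rbp4 (2.03), Apob (1.99), Hoxc6 (1.98), Dpp4 (1.93), Tfec (1.92), Plac1 (1.86), Prss35 (1.80) and Asb12 (1.75). Among pluripotency genes Pou5f1 fell by 0.82 (SE 0.24, adjusted p = 0.0344) and Fgf5 by 1.61 (SE 0.35, adjusted p = 0.00713) on the log2 scale. Nanog differed by -0.54 (adjusted p = 0.102, but 0.00566 with the replicate block within day and 0.000883 without treated replicate 2, in a range from 0.000883 to 0.583). Of the BMP genes fixed by name Smad6 rose by 0.81 (SE 0.19, adjusted p = 0.0119). Id1 (0.09, adjusted p = 0.794), Id2 (0.31, 0.154), Id3 (0.08, 0.801), Bmp4 (0.30, 0.25) and Msx2 (0.59, 0.183, but 0.0267 with the replicate block within day, in a range from 0.0267 to 0.69) did not pass. Rcan1 (0.04, adjusted p = 0.831), Ppp3ca (0.21, 0.0931, but 0.0348 without treated replicate 2, in a range from 0.00455 to 0.454), Ppp3cb (-0.07, 0.622) and Nfatc1 (-0.04, 0.847) did not pass. limma called 968 genes higher and 813 lower, and 1436 lower with the replicate block within day. Of the calls 54.4% were higher, against 71.3% after centring on the median. Counts were 245 higher and 173 lower without untreated replicate 2, 201 and 133 without treated replicate 1, 1769 and 1898 without treated replicate 2 and 386 and 238 without treated replicate 3. Without untreated replicate 3, 497 were lower. Each of these fits kept the same-numbered partner of the omitted array in the other group. Same-numbered arrays deviated together at day 8, so leaving out 1 array can also unbalance treated against untreated arrays. How far this moved the counts and adjusted p-values was not tested. With only the 6 day 8 arrays fitted, limma called 0 genes, with 3969 at an unadjusted p under 0.05. Asb12, Lgi1, Pax6, Pou5f1, Fgf5 and Smad6 lost their calls without treated replicate 1 or untreated replicate 2, Lgi1, Pax6, Pou5f1 and Smad6 without treated replicate 3, and Lgi1 and Pou5f1 without untreated replicate 3. These fits gave adjusted p-values from 0.0628 (Asb12) to 0.304 (Pou5f1), against 9.98e-06 to 0.304 over all their alternatives. Pou5f1 differed by -0.43 without treated replicate 1, and Pax6 had an adjusted p of 0.0727 under quantile normalization, in a range from 0.000937 to 0.219. With an intensity trend and robust prior Pou5f1 had one of 0.0643.

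Several programmes moved as groups at day 8. Neural progenitor genes fell by a mean of 0.42 on the log2 scale (0 of 30 higher, 15 lower, 0 and 17 adjusted over the list alone). Zic1, Sox1, En1 (-0.67) and Fezf2 (-0.79) led the list, which had camera's adjusted p = 2.22e-08 and adjusted p = 0.253 with an estimated correlation. Neuronal genes were lower by -0.26 (0 of 36 higher, 8 lower, 0 and 12 adjusted over the list alone). Map2, Gad2 (-0.62), Gad1 (-0.45) and Stmn2 (-0.79) led the list, which had adjusted p = 0.639 with an estimated correlation. Primed epiblast genes were lower by -0.65 (0 of 17 higher, 7 lower, 0 and 12 adjusted over the list alone). Zic2, Sall2 (-0.79), Fgf5 and Pim2 (-1.27) led the list, which had adjusted p = 0.31 with an estimated correlation. Naive pluripotency genes were lower by -0.31 (1 of 25 higher, 2 lower, 1 and 4 adjusted over the list alone). Pou5f1 and Utf1 (-0.88) passed, while Tbx3 went against the list at 0.77, and the list had adjusted p = 0.777 with an estimated correlation. Primitive streak genes were lower by -0.43 (0 of 19 higher, 3 lower, 0 and 7 adjusted over the list alone). Lhx1 (-1.24), Dll3 (-0.76) and Hes7 (-0.33) passed, and the list had adjusted p = 0.73 with an estimated correlation. BMP-Smad targets rose by 0.42 (9 of 24 higher, 0 lower, 10 and 0 adjusted over the list alone). Ptgs2 (1.38), Snai2 (1.18), Cdx2 (0.89) and Smad7 (0.51) led the list, which had camera's adjusted p = 2.22e-07 and adjusted p = 0.313 with an estimated correlation. Posterior Hox and Cdx genes, which mark the trunk and tail, rose by 0.79 (11 of 17 higher, 0 lower, 13 and 0 adjusted over the list alone). Hoxa9 (1.59), Hoxd8 (1.5), Hoxc8 (1.45) and Hoxc6 led the list, which had adjusted p = 0.114 with an estimated correlation. Mesenchyme and smooth muscle genes rose by 0.66 (11 of 26 higher, 0 lower, 14 and 1 adjusted over the list alone). Postn (2.96), Twist2 (1.51), Col1a1 (1.41) and Prrx1 (1.29) led the list, which had adjusted p = 0.282 with an estimated correlation. Endoderm genes rose by 0.50 (12 of 29 higher, 0 lower, 14 and 0 adjusted over the list alone). Dab2 (1.36), Rbp4, Apob and Hnf4a (0.65) led the list, which had adjusted p = 0.253 with an estimated correlation. Endothelial and blood genes rose by 0.34 (7 of 27 higher, 1 lower, 9 and 3 adjusted over the list alone). Cd34 (1.19), Eng (0.56) and Pecam1 (0.54) led the list, while Lmo2 went against the list at -0.56, and the list had adjusted p = 0.777 with an estimated correlation. Anterior Hox genes rose by 0.27 (5 of 18 higher, 0 lower, 6 and 0 adjusted over the list alone). Hoxc5 (1.36), Hoxd4 (0.98), Meis2 (0.80), Hoxc4 (0.42) and Hoxa5 (0.37) passed, the last named after its value was seen, and the list had adjusted p = 0.458 with an estimated correlation. The unfolded protein response list rose by 0.15 (8 of 20 higher, 0 lower, 9 and 0 adjusted over the list alone). Dnajc3 (0.51), Xbp1 (0.32), Pdia4 (0.27) and Pdia6 (0.26) led the list, which had adjusted p = 0.114 with an estimated correlation.

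Smaller shifts at day 8 included that of the calcineurin-NFAT component list, which rose by a mean of 0.08 (3 of 22 higher, 0 lower, 3 and 0 adjusted over the list alone). Rcan2 (0.40), Nfat5 (0.39) and Mef2a (0.27) passed, and the list had adjusted p = 0.639 with an estimated correlation. FGF-ERK response genes were lower by -0.20 (0 of 16 higher, 5 lower, 0 and 6 adjusted over the list alone). Dusp4 (-0.56), Il17rd (-0.49), Etv1 (-0.48), Spry1 (-0.47) and Spry2 (-0.45) passed, the last named after its value was seen, and the list had adjusted p = 0.777 with an estimated correlation. Cell cycle genes were lower by -0.13 (0 of 24 higher, 2 lower, 0 and 8 adjusted over the list alone). Ccne1 (-0.41) and Mcm2 (-0.26) passed, and the list had adjusted p = 0.777 with an estimated correlation. Hypoxia and glycolysis genes were lower by -0.16 (0 of 20 higher, 2 lower, 0 and 4 adjusted over the list alone). Adm (-0.57) and Hk2 (-0.33) passed, and the list had adjusted p = 0.777 with an estimated correlation. Cholesterol synthesis genes rose by 0.07 (1 of 16 higher, 0 lower, 1 and 0 adjusted over the list alone). Sc5d (0.30) passed, and the list had adjusted p = 0.795 with an estimated correlation. BMP ligands, receptors and antagonists were not called as a group (mean -0.11), but the receptors Bmpr2 (0.44) and Acvr1 (0.35) rose while the antagonists Chrd (-0.45), Nog (-0.44) and Cer1 fell, the first 4 named after their values were seen. Without treated replicate 1 camera's call ended for naive pluripotency (-0.10, adjusted p = 0.575), primitive streak (-0.18, 0.152), endothelial and blood (0.18, 0.0696), calcineurin (0.165), FGF-ERK (0.12), cell cycle (0.0755), hypoxia (0.399) and cholesterol genes (0.0661). Over the alternatives of these lists the highest adjusted p-values were 0.575, 0.152, 0.605, 0.205, 0.209, 0.0755, 0.399 and 0.205 in the same order, and the lowest lay between 1.66e-08 and 0.00675. The value of 0.605 was that of endothelial and blood genes without untreated replicate 2 (0.07), where calcineurin (0.192) and cholesterol genes (0.161) also lost their calls. Calls were further lost without untreated replicate 1 (calcineurin 0.0563, cholesterol 0.139), untreated replicate 3 (FGF-ERK 0.209) and treated replicate 3 (calcineurin 0.0595), under quantile normalization (0.205 for calcineurin and for cholesterol), and with only the 6 day 8 arrays fitted (naive pluripotency 0.0584, FGF-ERK 0.0669, hypoxia 0.124). Among genes above the 40th percentile of mean level the anterior Hox shift was 0.14 and not called (0.526, in a range from 5.02e-05 to 0.526). That filter also ended camera's calls of the calcineurin (0.147) and cholesterol lists (0.121). Both calls ended as well without the day 8 pair numbered 2 (0.0583 and 0.146). Of the 76 named calls at day 8, 38 ended without treated replicate 1, 35 without untreated replicate 2, 25 without treated replicate 3, 15 without untreated replicate 3, 6 without untreated replicate 1 and 0 without treated replicate 2. Among them were Fezf2, En1, Pim2, Cdx2, Lhx1, Dll3, Cd34, Rcan2, Nfat5, Mef2a, Ccne1, Adm, Dnajc3 and Sc5d without treated replicate 1, and Lmo2 without untreated replicate 1 (0.0698). The adjusted p-values without treated replicate 1 ran from 0.0509 (Cd34) to 0.378 (Rcan2), against 3.69e-06 to 0.378 over all alternatives. Zic1, Sox1, Map2, Gad2, Ptgs2, Dab2, Hnf4a, Col1a1, Twist2, Postn, Prrx1, Spry1, Hoxd4, Hoxc5, Hoxd8, Hoxa9 and Hoxc8 passed without each array in turn. All fits without 1 array kept its same-numbered partner in the other group, so calls could also end through the imbalance this leaves. Under other settings Hes7 had an adjusted p of 0.0534 with the replicate block within day (range 0.00468 to 0.23) and Pdia4 one of 0.21 with the mean of its probe sets (range 0.000534 to 0.21), and centring ended the calls of Dll3, Etv1, Adm, Hes7, Mcm2 and Hk2 (up to 0.0882, in a range from 0.000327 to 0.374).

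At day 12, 4 days after the drugs ended, the comparison asked whether earlier exposure had left neural genes lower. Pax6, which encodes a neural progenitor transcription factor (probe set 10474312), stood at 8.33 ± 0.40 in treated and 9.55 ± 0.23 in untreated EBs (-1.22, SE 0.16, adjusted p = 1.69e-05). Nes, which encodes the progenitor filament nestin, stood at 8.99 ± 0.36 and 10.08 ± 0.09 (-1.09, SE 0.17, adjusted p = 0.00012). The neuronal tubulin gene Tubb3 stood at 8.17 ± 0.10 and 9.04 ± 0.26 (-0.87, SE 0.10, adjusted p = 4.53e-06). Sox1 fell by 0.32 on the log2 scale (SE 0.09, adjusted p = 0.0117). Sim1, a transcription factor gene of hypothalamic neurons (probe set 10363056), had the largest fall named, from 9.74 ± 0.13 to 7.61 ± 0.39 (-2.13, SE 0.13, adjusted p = 4.19e-09). Next came Ptprz1 (-2.13), Fezf1 (-2.09), Ntn1 (-1.89), Dbx1 (-1.81), Pak3 (-1.80), Efcab1 (-1.80), Elavl4 (-1.79), Sim2 (-1.76) and Nrcam (-1.73). Pluripotency genes were higher after treatment, with Nanog at 10.50 ± 0.16 against 9.29 ± 0.31 (1.20, SE 0.20, adjusted p = 0.000243). Pou5f1 stood at 9.20 ± 0.16 against 8.04 ± 0.34 (1.16, SE 0.24, adjusted p = 0.00168), and Fgf5 differed by 0.41 (adjusted p = 0.481). Lrrc17 (probe set 10519998) had the largest rise named, from 9.10 ± 0.47 to 11.31 ± 0.71 (2.21, SE 0.40, adjusted p = 0.000431). Further rises were those of Prss35 (2.13), Ogn (2.12), Fmod (2.09), Npy1r (2.04), Gabra3 (1.99), Gpr50 (1.96), Brinp1 (1.84), Hpse2 (1.82) and Tbx4 (1.82). Of the BMP genes fixed by name, the 5 that stood higher at day 6 did not pass at day 12, with Msx2 at 0.05 (adjusted p = 0.933), Bmp4 at 0.28 (0.248), Id1 at -0.19 (0.493), Id2 at -0.10 (0.675) and Smad6 at 0.46 (0.108, and 0.0096 with the replicate block within day, in a range from 0.0096 to 0.295). Id3 fell by 0.50 on the log2 scale (SE 0.15, adjusted p = 0.0235). Rcan1 (-0.22, adjusted p = 0.167), Ppp3ca (0.01, 0.93), Ppp3cb (-0.12, 0.322) and Nfatc1 (0.03, 0.893) did not pass. limma called 1493 genes higher and 2070 lower, against 953 and 1361 without treated replicate 1, 919 and 1240 without treated replicate 3, and 1338 lower with only the 6 day 12 arrays fitted. Of the calls 41.9% were higher, against 51.9% after centring on the median (1893 higher and 1755 lower), so which direction held more genes depended on the scaling. Sox1 had an adjusted p of 0.102 without treated replicate 1 and 0.0533 under quantile normalization, in a range from 0.00193 to 0.102. Id3 had one of 0.106 without treated replicate 1 and 0.143 without treated replicate 3, in a range from 0.00301 to 0.143. Id3 also lost its call without untreated replicates 1 and 2, and Sox1 without untreated replicate 3.

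**Figure D2:**
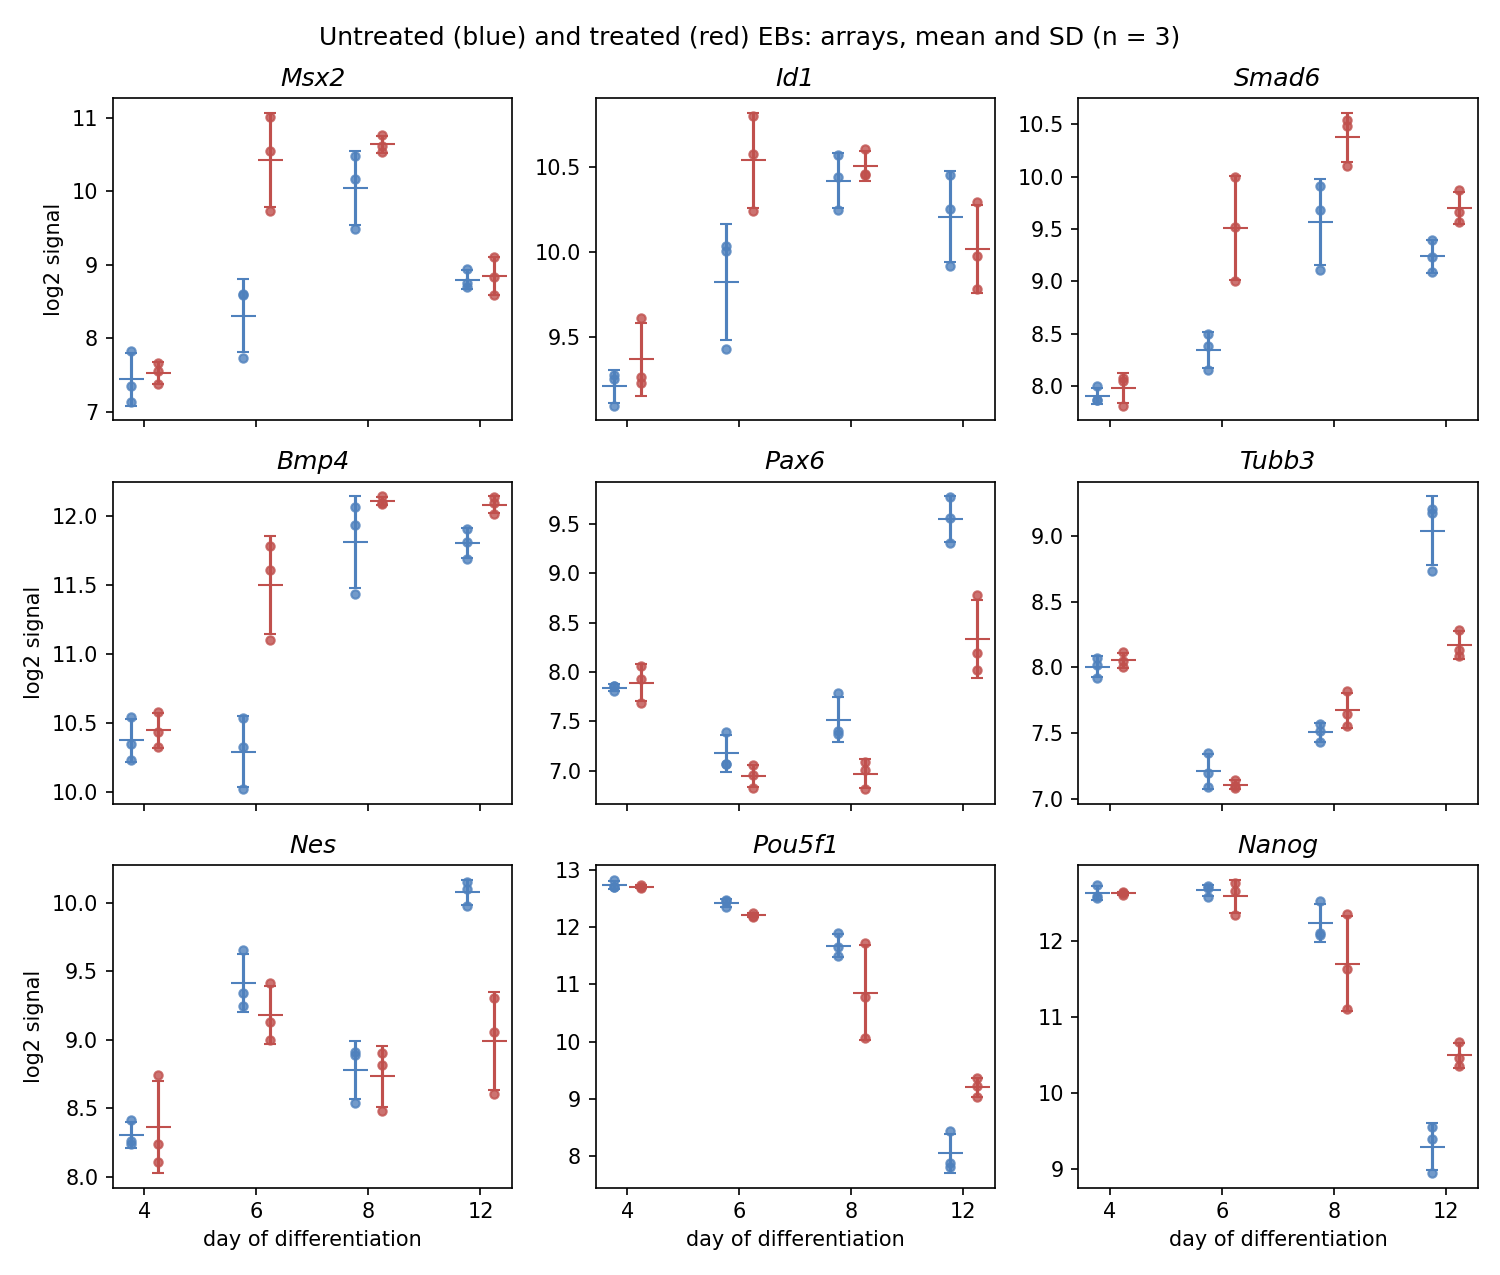
Log2 signal of 9 genes by day in untreated (blue) and treated (red) EBs, with a point for each array and the mean with its SD (n = 3). Msx2 stood at 10.43 in treated and 8.31 in untreated EBs at day 6, and Pax6 at 8.33 and 9.55 at day 12.

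Neural and neuronal genes fell as groups at day 12. The neuronal list fell by a mean of 0.76 on the log2 scale (0 of 36 higher, 28 lower, 0 and 30 adjusted over the list alone), with camera's adjusted p = 4.62e-23 and adjusted p = 0.114 with an estimated correlation. Its leading members were Map2 (9.22 ± 0.19 in treated and 10.61 ± 0.29 in untreated EBs), Dcx (7.77 ± 0.40 and 9.41 ± 0.45), Myt1 (-1.10) and Neurog2 (-1.04). The neural progenitor list fell by 0.66 on that scale (0 of 30 higher, 20 lower, 0 and 21 adjusted over the list alone). Olig2 (7.66 ± 0.22 against 8.73 ± 0.09), Fezf2 (-1.54), Dbx1 and Pax6 led the list, which had camera's adjusted p = 3.42e-14 and adjusted p = 0.114 with an estimated correlation. Notch response genes, active in dividing neural progenitors, were lower by -0.62 (0 of 13 higher, 10 lower, 0 and 10 adjusted over the list alone). Lfng (-1.13), Nrarp (-1.08), Hes5 (-0.73) and Notch1 (-0.71) led the list, which had adjusted p = 0.144 with an estimated correlation. Wnt response genes were lower by -0.39 (0 of 14 higher, 7 lower, 0 and 9 adjusted over the list alone). Apcdd1 (-1.25), Ccnd1 (-0.84) and Lef1 (-0.50) fell, and the list had adjusted p = 0.309 with an estimated correlation. Cholesterol synthesis genes were lower by -0.31 (0 of 16 higher, 11 lower, 0 and 13 adjusted over the list alone). Idi1 (-0.51), Lss (-0.47), Dhcr7 (-0.46) and Hmgcs1 (-0.41) led the list, which had adjusted p = 0.295 with an estimated correlation. Cell cycle genes were lower by -0.20 (0 of 24 higher, 11 lower, 0 and 18 adjusted over the list alone). Top2a (-0.30) and Kif11 (-0.29) fell, and the list had adjusted p = 0.458 with an estimated correlation.

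The lists that were higher in treated EBs at day 12 covered pluripotency, mesenchyme, endoderm and trophoblast. Mesenchyme and smooth muscle genes rose by 0.58 (11 of 26 higher, 1 lower, 16 and 1 adjusted over the list alone). Wt1 (9.32 ± 0.57 against 7.84 ± 0.27), Col3a1 (1.37), Col6a1 (1.16) and Col1a1 (1.09) led the list, which had adjusted p = 0.372 with an estimated correlation. Naive pluripotency genes rose by 0.54 (12 of 25 higher, 1 lower, 16 and 1 adjusted over the list alone). Dppa2 (1.61), Nanog, Dppa5a (1.14) and Tfcp2l1 (0.82) led the list, which had adjusted p = 0.458 with an estimated correlation. Endoderm genes rose by 0.51 (13 of 29 higher, 2 lower, 16 and 2 adjusted over the list alone), with adjusted p = 0.309 with an estimated correlation. The fetal serum protein genes Afp (9.82 ± 0.07 against 8.47 ± 0.17), Apoa1 (1.45) and Alb (1.24) led the list, while Foxa1 (-1.26) fell. Posterior Hox and Cdx genes rose by 0.57 (10 of 17 higher, 0 lower, 10 and 0 adjusted over the list alone). Hoxa10 (1.24), Hoxd10 (1.19) and Hoxd8 (0.95) led the list, which had adjusted p = 0.313 with an estimated correlation. Trophoblast genes rose by 0.27 (5 of 14 higher, 0 lower, 5 and 0 adjusted over the list alone). Plac1 (0.91), Hand1 (0.89), Tpbpa (0.59), Rhox9 (0.41) and Peg10 (0.27) passed, and the list had adjusted p = 0.313 with an estimated correlation. Nodal and activin response genes rose by 0.29 (3 of 10 higher, 1 lower, 6 and 1 adjusted over the list alone). Lefty1 (0.74), Pmepa1 (0.67) and Smad7 (0.36) passed, while Otx2 (-1.39) went against the list, and the list had adjusted p = 0.639 with an estimated correlation. Sall4 (-0.33) in the pluripotency list, Cxcr4 (-0.91) in the endoderm list and Foxc1 (-0.48) in the mesenchyme list also fell. These 3 and Plac1 as a trophoblast gene were named after their values were seen. BMP-Smad targets were not called (mean 0.17, 8 of 24 higher, 4 lower, 9 and 5 adjusted over the list alone, camera's adjusted p = 0.406 and adjusted p = 0.924 with an estimated correlation). Its members Id3 (-0.50), Id4 (-0.75), Dlx5 (-0.49) and Gata2 (-0.39) fell, the last 3 named after their values were seen. The call of the Nodal and activin list ended without untreated replicate 3 (adjusted p = 0.0513) and treated replicate 2 (0.0793), in a range from 0.00579 to 0.0793. Without treated replicate 1 the calls of Rhox9, Peg10, Hand1, Lefty1, Otx2, Smad7 and, in the falling lists, Lef1, Kif11 and 2 further cell cycle genes, Bub1b and Aurkb, ended at adjusted p-values from 0.0508 (Lef1) to 0.16 (Peg10). Leaving out another array ended 2 to 7 of those same calls at up to 0.179 (Smad7 without untreated replicate 1), against 1.75e-05 to 0.179 over all their alternatives.

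**Figure D3:**
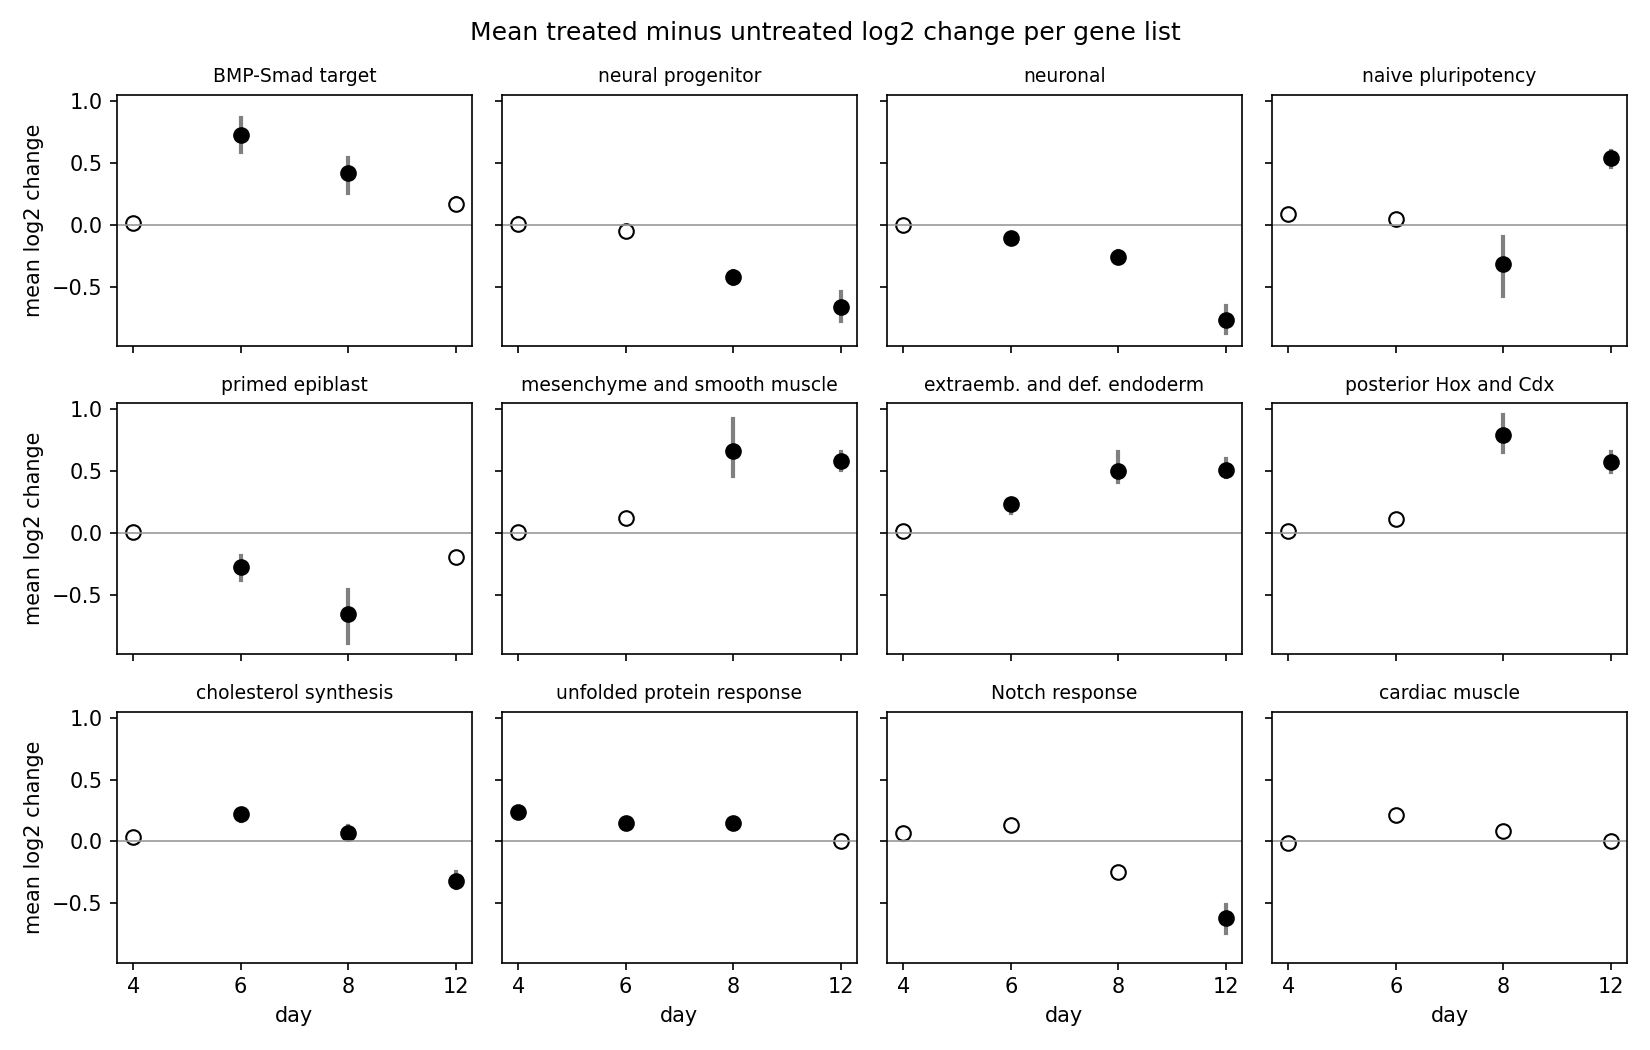
Mean log2 difference between treated and untreated EBs for 12 gene lists at each day, filled where camera with its preset correlation called the list and open where it did not, with grey bars from the lowest to the highest value with 1 array left out, drawn where computed. BMP-Smad targets lie at 0.72 at day 6 and neural progenitor genes at -0.66 at day 12.

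Of the 28 lists 4 were not called at any day by camera, and fry called 1 of these, housekeeping genes at day 8 (-0.06, adjusted p = 0.00227). Cardiac muscle genes (25 members) had mean shifts of -0.01, 0.21, 0.09 and 0.01 from day 4 to day 12, with camera's adjusted p of 0.0904, 0.0765, 0.269 and 0.825. Neural crest genes (14 members) had shifts of -0.02, -0.0012, -0.01 and -0.11 (adjusted p of 0.108, 0.766, 0.941 and 0.527), p53 response genes (17 members) of 0.03, -0.01, 0.02 and -0.02 (0.944, 0.832, 0.761 and 0.334) and housekeeping genes (12 members) of 0.03, 0.03, -0.06 and -0.02 (0.99, 0.705, 0.498 and 0.941). At day 8 the cardiac list had a mean above 0 and a median of -0.06, and at day 12 a mean of 0.01, a median of -0.03 and a test pointing down, while the neural crest list at day 8 had a mean and median under 0 and a test pointing up. The endothelial and blood list at day 12 had a mean of 0.10 and a median of -0.02, and the primitive streak list a mean of -0.02 and a median of 0.06. At day 4 the test pointed down for most lists with a mean just above 0, none of which was called. With an estimated correlation 1 list was called at day 4 and 0 on days 6, 8 and 12 by camera, whereas fry called 1, 5, 8 and 11 lists.

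**Figure D4:**
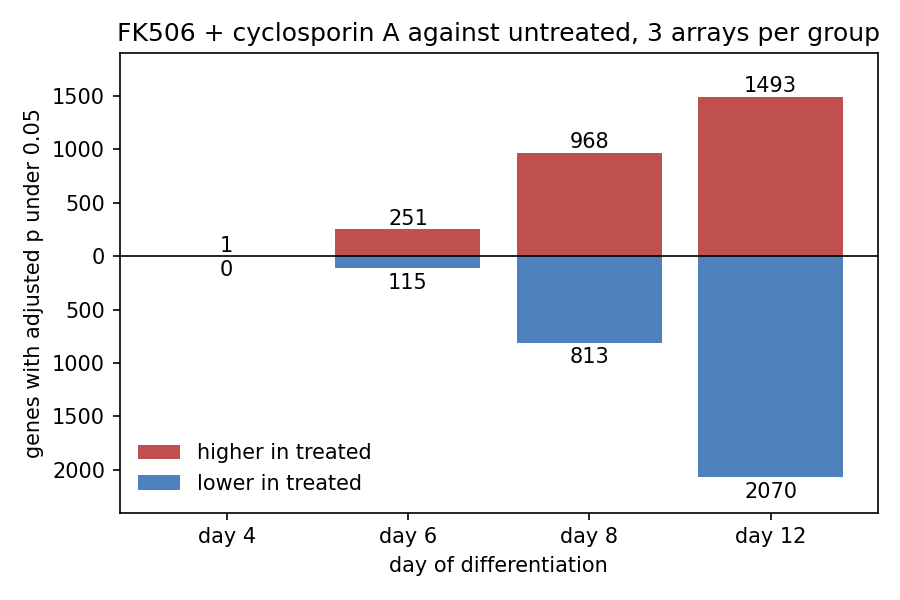
Number of genes higher (bars up) and lower (bars down) in treated than in untreated EBs at each day at an adjusted p under 0.05. Calls number 1 and 0 at day 4, 251 and 115 at day 6, 968 and 813 at day 8, and 1493 and 2070 at day 12.

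Days were compared with each other to see which genes stayed changed. The days share no arrays, but the model estimated each gene's variance over the arrays of all days. Between days 6 and 8, 64 genes were higher on both days where independent lists would share 12.2 (Fisher's exact p = 8.92e-29) and 39 were lower on both where 4.69 would be shared (exact p = 1.06e-25), with 0 in opposite directions. Between days 8 and 12, 344 genes were higher on both days (72.5 for independent lists) and 312 lower (84.4). Over those days 14 were higher then lower and 19 lower then higher. A gene with a low variance estimate can pass more easily on both days, and genes are not independent of each other. The counts for independent lists and the exact p-values leave this out, so how far the overlap exceeds chance was not tested. Across all genes, which are not independent replicates, the treatment effects correlated at r = 0.38 between days 6 and 8, 0.40 between days 8 and 12 and 0.09 between days 6 and 12. Averaged over the 4 days, 1637 genes were higher and 1244 lower in treated EBs. The effect itself differed between day 4 and day 6 for 19 genes, between day 6 and day 8 for 80 and between day 8 and day 12 for 1037.

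The treatment effect of each day was set against the untreated change between other days, again across genes and with no shared array, to ask whether treated EBs lay ahead of or behind untreated ones. Days 6 and 8 were set against the change from day 4 to day 12, day 4 against that from day 6 to day 12, and day 12 against that from day 4 to day 8. The correlation was -0.04 at day 4 (jackknife SE 0.13), 0.24 at day 6 (SE 0.084), 0.42 at day 8 (SE 0.138) and 0.08 at day 12 (SE 0.077). Other splits of the 6 arrays of each day reached absolute values of 0.17, 0.33, 0.59 and 0.16, and 9, 3, 5 and 3 of the 10 splits were as large as the real one. Among the 4 splits that part all 3 numbered pairs, other splits reached 0.20 at day 6, 0.45 at day 8 and 0.16 at day 12, and 1, 2 and 2 of the 4 were as large. At days 8 and 12 the value thus did not stand apart by either count, and at day 6 only the real split reached it among those that part the pairs, where 4 splits are too few for a share under 0.05. The day 12 value could hardly show a delay of neural genes, since it used the change from day 4 to day 8. In untreated EBs the neural progenitor and neuronal lists moved by 0.15 and -0.24 over those days. They moved by 1.02 and 1.27 from day 8 to day 12. Spearman's rho at day 6 was 0.12.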

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

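The tests of scaling and of position along the time course for the day 6 BMP pattern, both tests of the day 12 pattern and all splits without a whole-day exchange were chosen only after the result was seen. In these groups of 3 no search for outlying arrays was made, and each array was left out in turn.

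Treatment effects differed between days by a test of the difference itself. The lists given as moved are those that both camera and fry called on that difference. Between day 4 and day 6 the effect differed for 19 genes, Msx2 (2.03, adjusted p = 0.0374) and Bmp4 (1.13, adjusted p = 0.0417) among them, and BMP-Smad targets moved by 0.71 more at day 6 (camera's adjusted p = 9.97e-18, adjusted p = 0.28 with an estimated correlation). Between day 6 and day 8 it differed for 80 genes. Posterior Hox and Cdx genes moved by 0.68 more at day 8 (5.44e-12, 0.28 with an estimated correlation), while primitive streak (-0.83, 1.1e-11, and 0.317), Wnt response (-0.55, 1.86e-07, and 0.28) and BMP ligand, receptor and antagonist genes (-0.29, 0.00425, and 0.317) moved down from day 6 to day 8. Camera but not fry called further lists there, among them mesenchyme (0.54), endothelial and blood (0.40), endoderm (0.26) and neural progenitor genes (-0.38). Between day 8 and day 12 it differed for 1037 genes, among them Nes (-1.04, adjusted p = 0.015), Tubb3 (-1.03, adjusted p = 0.00032), Pou5f1 (1.98, adjusted p = 0.00217), Nanog (1.74, adjusted p = 0.00168) and Fgf5 (2.02, adjusted p = 0.0212). Neuronal genes (-0.51, camera's adjusted p = 6.16e-12), cholesterol synthesis genes (-0.39, 2.21e-11) and the unfolded protein response (-0.14, 9.48e-04) moved down over those days. Naive pluripotency (0.85, 2.16e-10), Nodal-activin (0.90, 4.49e-04) and trophoblast genes (0.27, 0.00877) moved up, with adjusted p = 0.317 with an estimated correlation for each of these 6 lists.

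Other groupings of the same arrays matched the interaction counts. Of 100 splits within both days, 10 gave as many genes as the 19 between day 4 and day 6 (highest other 151), 7 as many as the 80 between day 6 and day 8 (1373) and 5 as many as the 1037 between day 8 and day 12 (4428). These splits thus did not exclude chance for any of the 3 counts. The 151 came from exchanging all labels of 1 day, and without such an exchange 9, 7 and 4 splits were as large, with highest others of 91, 1373 and 4428. Of the 32 splits that part all 3 numbered pairs in both days, 3 reached the 80 (2 without an exchange, highest 337) and 4 reached the 1037 (3 without, highest 1988). Counts several times the real one point to a structure of the arrays, of which treatment itself can be part, since exchanging all labels of 1 day adds the effects of both days and gave 2176 genes (day 6 to 8) and 4150 (day 8 to 12). Exchanging only some labels of 1 day can do the same in part. The splits therefore do not stand for an equal effect on both days and cannot decide on chance for the interactions. Leaving out 1 array moved the 19 at day 4 to 4, 5 and 8 (untreated replicates 1, 2 and 3) and 10, 5 and 5 (treated), and at day 6 to 35 and 5 (untreated replicates 1 and 2) and 4, 66 and 6 (treated replicates 1, 2 and 3). It moved the 80 at day 6 to 11 and 32 (untreated replicates 2 and 3) and 22 and 22 (treated replicates 1 and 3), and at day 8 to 248, 41 and 11 (untreated replicates 1, 2 and 3) and 9, 1102 and 19 (treated). It moved the 1037 at day 8 to 566 (untreated replicate 2) and 660, 1907 and 535 (treated replicates 1, 2 and 3), and at day 12 to 666 and 685 (untreated replicates 2 and 3) and 662, 1724 and 498 (treated).

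In probe sets outside the report's comparisons, limma called 57 of 1621 with several gene symbols and 144 of 12146 with no listed gene at day 12.

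The first pattern weighed is the rise of BMP-Smad targets in treated EBs at day 6. Scaling of the arrays was weighed as its cause, and the mean shift under quantile normalization was 0.68 against 0.72. That step moved the median of all genes at day 6 by only -0.0077, so it could hardly have removed the shift. It shows only that the shift did not depend on this step. Treated EBs may also lie ahead along the untreated course, where BMP-Smad targets rise by day 8. The shift made up 0.70 of the list's untreated change from day 4 to day 8, against 0.52 for Wnt response genes, the highest of the 11 other rising lists, a margin of 0.18 (jackknife SE 0.15, and 0.10 to 0.30 with 1 array left out). Shares went down to -0.06 (endothelial and blood), and naive pluripotency genes, which fell by 0.93 on the log2 scale over those days in untreated EBs, differed by a mean of 0.044 (median -0.01) at day 6. That list holds Tbx3, which is also a member of the BMP-Smad list. Primed epiblast genes (-0.32 over those days in untreated EBs, -0.27 at day 6) and trophoblast genes (0.46 and 0.31) moved along the course. Their shares were 0.84 and 0.67, but camera did not call their untreated change (adjusted p = 0.0708 and 0.142). Camera did not call the trophoblast shift at day 6 either (median 0.06, 8 of 14 members above 0, adjusted p = 0.0566). The trophoblast list holds Hand1, which is also a member of the BMP-Smad list. The margin is too close to its error to decide and lists need not change at an equal pace, so a response specific to BMP targets and a more advanced stage cannot be told apart.

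The second pattern is the fall of neural and rise of naive pluripotency genes at day 12. A delay of the whole culture would hold back the lists that rise late in untreated EBs, but mesenchyme and smooth muscle genes, which rose by 1.16 from day 8 to day 12 (adjusted p = 0.258 with an estimated correlation), stood 0.58 higher in treated EBs (0.51 to 0.66 with 1 array left out, adjusted p = 0.372 with an estimated correlation). A lower share of neural cells alone would raise the markers of other cell types alike, but the mesenchyme shift exceeded the cardiac one by 0.57 (jackknife SE 0.23). The mesenchyme and cardiac lists were picked for these tests after their shifts were known. The endoderm (0.51) and naive pluripotency (0.54) shifts lay close to the mesenchyme one, and that of trophoblast genes (0.27) lay below it. Besides the cardiac list, camera did not call endothelial and blood (0.10, median -0.02), primitive streak (-0.02, median 0.06) or neural crest genes (-0.11) at day 12. A pair of lists picked afterwards cannot decide the question, so a lower share of neural cells stays open. A fate change from neural to mesenchymal cells, a delay of some cells and a change within the mesenchyme stay open as untested explanations.

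The third pattern is the rise of unfolded protein response genes at day 4, 1 day after the drugs were added. An effect of treated replicate 1, the array furthest from its group, is argued against, since the mean shift without it was 0.21 against 0.23. Under quantile normalization the shift was 0.20. That step moved the median of all genes at day 4 by only -0.031, so it could hardly have removed the shift and does not decide on scaling. A response of the cells to the drugs may explain it, and whether that would run through calcineurin or through another effect of the compounds was not tested.

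For every comparison of 3 arrays against 3, 1 of the 10 splits, the real one, gave a result as large, and 10 splits are too few for a share under 0.05. The real value and the highest other were 1 and 0 genes at day 4, 366 and 0 at day 6, 1781 and 1611 at day 8 and 3563 and 92 at day 12. For the untreated EBs they were 8379 and 0 (day 4 to 6), 7197 and 0 (day 6 to 8), 7714 and 1 (day 8 to 12) and 11410 and 0 (day 4 to 12). The list shifts were 0.23 against 0.11 for the unfolded protein response at day 4, 0.72 against 0.50 for BMP-Smad targets at day 6, -0.42 against 0.28 for neural progenitors at day 8 and -0.66 against 0.38 at day 12. The split with 1611 genes at day 8 parts fewer pairs than the real one, and among splits that part all 3 numbered pairs the highest other was 0 at day 8 and 1 at day 12. With all 4 days averaged, 1 of 100 splits within days, the real one, gave as many as 2881 genes (highest other 314). These splits regrouped the arrays of each day apart from those of the other days. Whether a number marks the same experiment on every day is not known. If it does, 3 experiments allow too few splits for a share under 0.05. Chance is thus excluded for the average effect only if the days are independent of each other.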

How the results depend on the processing

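The fits with a replicate block within day and without the day 8 pair numbered 2 were tests chosen only after the data were seen. Of 242 calls of named genes 0 reversed in any setting, 76 ended when some array was left out, and 92 ended with the compared groups fitted alone, which leaves fewer residual degrees of freedom. Quantile normalization ended 9, centring on the median 8, an intensity trend with robust prior 9, the mean of probe sets 1 and array weights 0, and the 40th percentile filter ended 0 of the 198 calls it could test. Unless stated, the cause of a change was not tested. A 2-fold threshold left 0 genes higher at day 4, 58 and 3 (higher and lower) at day 6, 129 and 35 at day 8 and 164 and 120 at day 12, 281 and 84, 186 and 127, 648 and 243, and 1547 and 838 in the untreated contrasts in the order of the report, 47 and 188 in the last 2 interactions, and 6 on average over the days. Above the 40th percentile, where fewer genes are tested, 6 genes were higher at day 4, 1994 lower from day 4 to day 6 and 1897 higher from day 6 to day 8, and the neural progenitor shift at day 4 was -0.0037. Under quantile normalization 0 genes were higher at day 4 (1093 at an unadjusted p under 0.05 in limma) and 8 differed between days 4 and 6, Ppp3cb at day 6 was -0.0017, Nfatc1 at day 8 was 0.0063, and the neural progenitor and BMP-Smad shifts at day 4 were -0.021 and -0.022. Centring gave 1508 genes higher at day 8, 7297 lower from day 4 to day 6, 7357 from day 8 to day 12 and 10836 from day 4 to day 12, Nfatc1 at day 8 at 0.00018, and those day 4 shifts at -0.022 and -0.018. It made 72.4% of the calls between days 6 and 8 positive, and quantile normalization 67.0%, against 55%. An intensity trend gave 5 genes higher at day 4 and 10 between days 4 and 6. Array weights, whose estimation gave a convergence warning, called 100 and 43 genes at day 4, 668 and 624 at day 6, 2140 and 3018 at day 8, 614, 1390 and 3201 in the interactions and 5173 on average, with Nfatc1 at day 8 at 0.0085 and Msx2 at day 12 at -0.012. With the compared groups alone, limma called 0 genes at day 4 (806 at an unadjusted p under 0.05), 0 higher and 0 lower at day 8 (3969), 1338 lower at day 12, and 5, 3 and 224 in the interactions. Without the day 8 pair numbered 2, 601 genes differed between days 6 and 8, Nes at day 8 was 0.14 and Id1 -0.051. With an estimated correlation camera did not call BMP-Smad targets at day 6 (0.72, adjusted p = 0.114) and day 8 (0.42, 0.313) or neural progenitors at day 8 (-0.42, 0.253) and day 12 (-0.66, 0.114). Spearman's correlation with the time course at day 6 was 0.12.

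Replicate numbers did not pair the day 4 arrays (correlations of -0.01, 0.19 and -0.05, with 1 of 3 numbers correlating best with itself). The replicate block over all days gave 60 genes between days 4 and 6 and 203 between days 6 and 8. The replicate block within day gave 0 genes higher at day 4 in limma (1528 at an unadjusted p under 0.05), 418 higher and 303 lower at day 6, 1436 lower at day 8, and 161, 648 and 1970 in the interactions, and the blocks changed no other call than those of Usp11 at day 4 (adjusted p = 0.154), Nfatc1 at day 6, Hes7, Nanog and Msx2 at day 8 and Smad6 at day 12.

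With 1 array left out, genes higher and lower ranged over 0 to 1 and 0 to 0 at day 4, 79 to 246 and 19 to 129 at day 6, 201 to 1769 and 133 to 1898 at day 8, and 919 to 1791 and 1240 to 2533 at day 12. In untreated EBs they ranged over 3404 to 3972 and 2635 to 4092 (day 4 to 6), 1940 to 3476 and 2543 to 3336 (day 6 to 8), 3157 to 3574 and 3023 to 3854 (day 8 to 12), and 5073 to 5232 and 5171 to 6101 (day 4 to 12). The interactions ranged over 4 to 66, 9 to 1102 and 498 to 1907, and the average over 2282 to 3810. BMP-Smad shifts ranged from -0.015 to 0.040, 0.59 to 0.86, 0.26 to 0.54 and 0.14 to 0.22 from day 4 to day 12, neural progenitor shifts from -0.026 to 0.054, -0.08 to -0.03, -0.48 to -0.37 and -0.77 to -0.54, and the time course correlations from -0.10 to 0.06, 0.18 to 0.28, 0.32 to 0.49 and 0.03 to 0.11. Uncalled genes changed sign for Nanog (-0.16 to 0.041) and Ppp3cb (-0.014 to 0.083) at day 6, Nes (-0.17 to 0.082), Id3 (-0.0042 to 0.16), Rcan1 (-0.034 to 0.12) and Nfatc1 (-0.13 to 0.021) at day 8, and Msx2 (-0.085 to 0.17) and Ppp3ca (-0.0083 to 0.031) at day 12.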

Other observations

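The test of day 8 arrays below was chosen only after the result was seen.

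Both arrays numbered 2 deviated in the same direction at day 8, whether treated or not. Replicate experiments may have stood at different points of the time course by then: across genes, the mean deviation of the pair numbered 2 correlated at -0.61 with the untreated change from day 4 to day 12, with -0.46 for its untreated and -0.59 for its treated array. The pairs numbered 1 and 3 had 0.44 and 0.36, which add no separate evidence, since the 3 deviations of a group sum to 0. The largest distances of single arrays from their group were 0.171 for treated day 8 replicate 2, 0.15 for treated day 4 replicate 1 and 0.148 for treated day 8 replicate 1 (root mean square, log2).

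Between day 6 and day 12, 46 genes were higher on both days (18.8 for independent lists) and 26 lower (11.9), while 17 were higher then lower and 5 lower then higher. Here too the counts for independent lists leave out the shared variance estimate and the dependence between genes. The 3 genes at least 2-fold lower at day 6 were Tmem154, Exoc3l and Klhl4.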
